A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

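RNA from 6 samples of Saccharomyces cerevisiae W303 was extracted with a silica column kit and made into Illumina TruSeq libraries, per the labels' protocols. Reads were processed with TopHat2 2.0.9, Bowtie2 2.1.0, SAMtools 0.1.18, Cufflinks 2.2.0 and Cuffdiff 2.2.0 on the sacCer3 (R64) genome, per the submitters' processing notes, which give no role or order for each tool. The counting tool, its strand setting and the annotation release are not given in the sources used here. The deposited count table holds whole-number counts per Cufflinks locus, not normalized, and the deposited FPKM table holds the same loci as FPKM, scaled for length and depth, per the file headers and values. The deposited merged transcript models place the 6931 loci on the genome. Of these, 6816 hold 1 gene and 115 hold several genes, which were kept as a single locus and named by all of their genes. Start and end equalled those of the R64 reference annotation for 99.68% of the shared genes, and no exon lay past the end of a reference chromosome. The positions serve only for coordinates, overlaps and upstream sequence.

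Samples were grouped by the treatment named in the labels, with 2 samples per group and 1 column per sample. Nothing in the labels says that the 2 samples of a group came from separate cultures, so p-values measure the spread between these samples, which could be technical. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 7.18 in WT, 3.02 in PSD1 overexpression and 5.91 in pdr3Δ. Their log2 CPM correlated across genes at 0.9956, 0.9969 and 0.9964, against 0.9609 to 0.9904 between groups. The first principal component held 76.1% of the variance and separated WT from the other groups. Total counts per library ran from 10220872 to 12315448, and the mitochondrial genome took at most 0.003% of counts, so its transcripts were not described here.

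Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling (factors 0.99 to 1.012), edgeR's expression filter by group and the quasi-likelihood test over all 6 libraries. This left 6171 loci, 3 residual degrees of freedom, a common dispersion of 0.00217 and a biological coefficient of variation of 4.66%. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg). With so small a spread, calls were made at small changes, down to an absolute log2 fold change of 0.118 in PSD1 overexpression against WT. Comparisons with WT also differ in the galactose genes and in URA3, whose values stand beside them.

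Gene lists for the pathways that fit this yeast and treatment were fixed before the data were examined. They were tested with camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg over the lists), beside camera with an estimated correlation and fry. No list kept its camera call with an estimated correlation in any comparison. In simulated data a list of 25 genes, drawn independently and shifted by log2 0.5, was tested with an estimated correlation. It reached an unadjusted p of 0.00132, 0.00158 and 0.00141 in the 3 comparisons. The simulation left out correlation between members. In PSD1 overexpression against WT that was estimated at 0.122 for general stress, 0.3 for heat shock and 0.35 for respiratory genes. It therefore cannot say how much room that test leaves the real lists. The named genes were also set before the data were examined: PSD1, PDR3, PDR1, CIS1, MSP1, TOM70 and PDR5 in every comparison, the 8 largest rises and falls per comparison among called genes whose libraries did not overlap between groups and whose mean log2 CPM was at least 2, and up to 4 members per list described by smallest p. SNQ2, YOR1 and PDR16, the list members GAL4 and NDE2, and the genes in the closing observations were named after their values were seen.

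The test was checked on simulated counts for the same 6171 genes, with 50 genes changed at each of 4 sizes. At log2 changes of 0.25, 0.5, 1 and 2 it recovered 32%, 84%, 98% and 96% of them for PSD1 overexpression against WT, 36%, 88%, 100% and 100% for pdr3Δ against PSD1 overexpression, and 44%, 88%, 96% and 98% for pdr3Δ with overexpression against WT. False calls made up 4.8%, 6.7% and 6.1% of calls. The simulated data gave 186, 195 and 197 calls, far fewer than the 3443, 1291 and 2415 in the measured data. Fewer calls make the Benjamini-Hochberg cutoff stricter, so recovery of small changes may be understated. For comparisons that share libraries, 20 sets of counts with no changed genes were drawn from the genes' own means and dispersions. They gave a mean of 1.25, 1.7 and 2.05 calls.

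The alternatives were DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), RLE size factors, library totals alone, no filter, a minimum of 50 counts in 2 libraries, library sizes without PSD1, ribosomal RNA and mitochondrial genome genes, a replicate block, each replicate left out in turn, fits with only the groups compared, and a 2-fold minimum. Library sizes without PSD1, URA3 and the galactose genes were added after the data were seen, as were fits in which each comparison took its own PSD1 overexpression library, with the spread taken from the other 2 groups. Response elements for Pdr1 and Pdr3 (TCCGYGGR, either strand) were searched within 500 bp upstream of single-gene loci in the R64 sequence. Tables were handled and plots drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.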

Results

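Gene expression was measured by RNA sequencing of 6 samples of the budding yeast Saccharomyces cerevisiae strain W303, a common laboratory background. The samples fell into 3 groups of 2: a wild-type control (WT), cells that overexpressed PSD1 from a GAL promoter on a 2µ plasmid, and cells that overexpressed PSD1 and lacked PDR3 (pdr3Δ). PSD1 encodes the phosphatidylserine decarboxylase of the mitochondrial inner membrane, and PDR3 encodes a zinc cluster transcription factor of drug resistance genes. The study asked how cells respond when mitochondrial protein import is stressed. Cells were grown in medium with 1% yeast extract, 2% peptone and 2% raffinose, and PSD1 was induced with 2% galactose for 4 h. The labels give this treatment for all 6 samples, WT included, but mark the induction as plus or minus and do not say which samples were which. Total counts were 11628639 and 12315448 in WT, 11382036 and 10220872 in PSD1 overexpression, and 11991405 and 11341144 in pdr3Δ. Of 6931 loci, 6171 were tested. All coordinates are on the R64 (sacCer3) build, and levels are CPM, the counts scaled to library size, ± SD. Log2 fold changes are mostly given ± SE, with n = 2 per group. The SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. It can be too small for large changes from few counts. With 12 and 11 counts in WT, the gene CIS1 had an SE of 0.15 at log2 7.17 but 0.34 at log2 1.31.

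PSD1 and PDR3 were read first, in every library. PSD1 (YNL169C, chromosome XIV, 316169 to 317671) reached 1494.8 and 1318.8 CPM in WT, 14465.8 and 16489 CPM in PSD1 overexpression, and 9369.9 and 9070.9 CPM in pdr3Δ. PDR3 (YBL005W, chromosome II, 217470 to 220400) had 724 and 798 counts in WT, 2283 and 2245 in PSD1 overexpression, and 3 and 9 in the pdr3Δ libraries. By counts, not corrected for gene length, PSD1 thus ranked 1 among tested loci in both PSD1 overexpression libraries and 66 and 84 in WT. It overlaps YNL170W on the opposite strand over 205 bp, and the strand setting of the counting is not given in the sources used here.

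The first comparison asked which genes respond to PSD1 overexpression. PSD1 rose 11-fold against WT (log2 3.46 ± 0.10, edgeR adjusted p = 3.51e-09), and the drug resistance genes CIS1 and PDR5 rose with it. CIS1 (YLR346C, chromosome XII, 822287 to 822592), a small gene that Pdr3 activates, rose 144-fold (7.17 ± 0.15, adjusted p = 6.29e-10), from 0.97 ± 0.102 to 141 ± 12.0 CPM. PDR5 (YOR153W, chromosome XV, 619840 to 624375), the main drug efflux pump of the plasma membrane, rose 9.68-fold (3.28 ± 0.09, adjusted p = 3.35e-09). Most listed heat shock (22 of 22) and general stress genes (27 of 30) were higher as well, and most respiratory (36 of 37), ribosomal protein (135 of 137) and G1/S genes (16 of 20) were lower. With an estimated correlation none of these lists passed (adjusted p = 0.103 to 0.16). PDR3 itself rose 3.28-fold (1.72 ± 0.08, adjusted p = 7.7e-08), whereas its paralog PDR1 (YGL013C, chromosome VII, 469092 to 472298) rose by 0.26 ± 0.05 (adjusted p = 0.00107). MSP1 (YGR028W, chromosome VII, 542203 to 543291), the ATPase that extracts proteins from the outer membrane, rose by 0.21 ± 0.05 (adjusted p = 0.00881). The import receptor gene TOM70 (YNL121C, chromosome XIV, 398684 to 400537) fell by 0.23 ± 0.06 (adjusted p = 0.0099). These 2 small changes lost their call when single libraries were left out, MSP1 without PSD1 overexpression library 2 (adjusted p = 0.0527) and TOM70 without WT library 1 (0.0567) or PSD1 overexpression library 1 (0.0941).

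Outside those genes, and among genes above the fixed level, the largest rises were in the galactose genes GAL7 (8.59 ± 0.31), GAL10 (7.77 ± 0.24), GAL2 (7.71 ± 0.25) and GAL1 (7.68 ± 0.27), which encode the enzymes and the permease of galactose use. GAL1 (YBR020W, chromosome II, 279021 to 280607) had 484 and 230 counts in WT against 72738 and 61306 in PSD1 overexpression. The next were HSP26, a small heat shock chaperone (5.16 ± 0.16), the hydrophilin genes SIP18 (4.54 ± 0.22) and GRE1 (4.15 ± 0.30), and YMR175W-A, which lies next to SIP18 (4.06 ± 0.34). GRE1 had 92 and 279 counts in WT against 2953 and 3000 in PSD1 overexpression, so the size of its rise is uncertain. Among genes above the fixed level, the largest falls were in JEN1, the lactate and pyruvate transporter (-1.96 ± 0.05), YIG1 (-1.83 ± 0.09), the glucose-repressed alcohol dehydrogenase gene ADH2 (-1.75 ± 0.14), the cell wall gene CWP1 (-1.75 ± 0.11), YML090W (-1.69 ± 0.11), YGR067C (-1.60 ± 0.08), SPS4 (-1.56 ± 0.13) and ACH1, a mitochondrial CoA transferase (-1.53 ± 0.09). YML090W overlaps YML089C on the opposite strand over 90 bp. Adjusted p lay between 3.02e-09 and 4.61e-06 for these 16 genes.

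**Figure D1:**
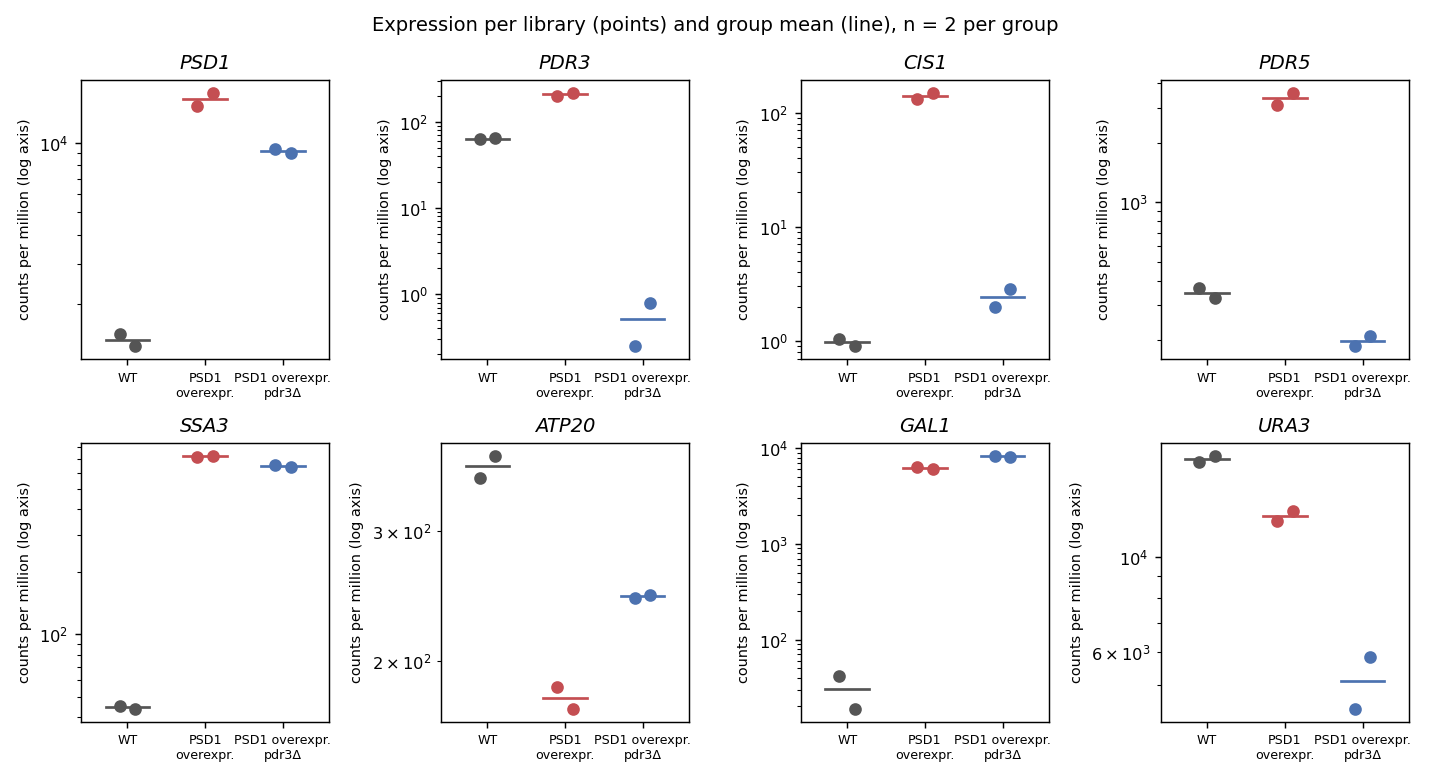
CPM (log axis) of 8 genes in each of the 6 libraries (points), with the group mean as a line and n = 2 per group. CIS1 and PDR5 were high in PSD1 overexpression and far lower in pdr3Δ, SSA3 and GAL1 stayed high in both overexpressing groups, ATP20 was lowest in PSD1 overexpression, and URA3 was lowest in pdr3Δ.

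Of 23 tested targets of Pdr1 and Pdr3, 21 were higher and none was lower, and 21 were higher adjusted over the list alone (camera adjusted p = 1.62e-27; adjusted p = 0.103 with an estimated correlation). GRE2, a methylglyoxal reductase, rose by 3.15 ± 0.08 and PDR15/YDR406W-A, a locus with an ABC transporter gene, by 3.45 ± 0.10. Of 18 drug and weak acid transporter genes outside that list 7 were higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.65; adjusted p = 0.713 with an estimated correlation). All 22 cytosolic heat shock genes were higher, also 22 adjusted over the list alone (camera adjusted p = 1.84e-55; adjusted p = 0.103 with an estimated correlation), led by the Hsp70 genes SSA3 (4.02 ± 0.05) and SSA4 (2.99 ± 0.08) and the nucleotide exchange factor gene SSE2 (2.58 ± 0.06). Of 30 general stress genes, 27 were higher and 1 was lower, with the same counts adjusted over the list alone (camera adjusted p = 8.17e-40; adjusted p = 0.103 with an estimated correlation). SOL4 rose by 2.61 ± 0.06 and the glutamate decarboxylase gene GAD1 by 2.13 ± 0.05. All 32 proteasome genes were higher, 32 adjusted over the list alone (camera adjusted p = 3.4e-06; adjusted p = 0.273 with an estimated correlation), with a median of 0.35. Of 20 oxidative stress genes 11 were higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.000493; adjusted p = 0.153 with an estimated correlation), led by the peroxiredoxin gene AHP1 (2.46 ± 0.09). Galactose genes differed between the same libraries, with 10 of 11 higher and 1, GAL4, lower, the same adjusted over the list alone (camera adjusted p = 2.6e-31; adjusted p = 0.103 with an estimated correlation).

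Among mitochondrial genes, the direction differed by function. Of 37 nuclear genes of the respiratory chain and ATP synthase, 36 were lower and 1, the external NADH dehydrogenase gene NDE2, was higher, with the same counts adjusted over the list alone (camera adjusted p = 2.02e-26; adjusted p = 0.16 with an estimated correlation). COX4 fell by 1.01 ± 0.05 and ATP20 by 1.04 ± 0.05. Of 20 genes of the tricarboxylic acid cycle 18 were lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 1.56e-11; adjusted p = 0.16 with an estimated correlation), with FUM1 at -1.12 ± 0.06. Of 20 mitochondrial chaperones and proteases, 9 were higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.00171; adjusted p = 0.243 with an estimated correlation). HSP78, the disaggregase, rose by 1.87 ± 0.07, HSP10 by 1.49 ± 0.05 and HSP60, its chaperonin partner, by 1.25 ± 0.08. The 38 import genes had no common direction, with 10 higher, 8 lower and 20 not passing, and 10 and 8 adjusted over the list alone (camera adjusted p = 0.925; adjusted p = 0.933 with an estimated correlation), a median of -0.01 and a mean of 0.03. MIA40, the oxidoreductase of the intermembrane space, rose by 0.74 ± 0.05. TIM11 fell by 0.87 ± 0.07, and it is counted in this list although it encodes a subunit of the ATP synthase. Of 70 mitochondrial ribosome genes, 43 were higher and 6 lower, and 45 and 6 adjusted over the list alone (camera adjusted p = 0.00201; adjusted p = 0.243 with an estimated correlation). Targets of the retrograde factors Rtg1 and Rtg3 were lower for 5 of 8 and higher for 2 (camera adjusted p = 0.00751, or 0.345 with an estimated correlation). Glucose-repressed and Snf1-dependent genes were lower for 9 of 18 and higher for 1 (camera adjusted p = 0.00275, or 0.432 with an estimated correlation). Both lists had the same counts adjusted over the list alone. GAL1 was about 205-fold higher in the same PSD1 overexpression libraries.

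Of 137 cytosolic ribosomal protein genes 135 were lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 1.84e-55; adjusted p = 0.16 with an estimated correlation), with RPS22B at -1.03 ± 0.05. Of 62 ribosome biogenesis genes 57 were lower and none higher, and 60 were lower adjusted over the list alone (camera adjusted p = 6.63e-09; adjusted p = 0.459 with an estimated correlation). Of 20 G1/S genes 16 were lower and none higher, the same adjusted over the list alone (camera adjusted p = 1.01e-05; adjusted p = 0.103 with an estimated correlation), among them the cyclin genes CLN1 (-0.88 ± 0.05) and CLN2 (-0.85 ± 0.06) and the ribonucleotide reductase gene RNR1 (-0.84 ± 0.05). Of 18 glycolysis and fermentation genes 17 were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 2.16e-09; adjusted p = 0.273 with an estimated correlation), with PGK1 at 1.54 ± 0.07. Of 16 genes of the unfolded protein response of the endoplasmic reticulum 8 were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.0963; adjusted p = 0.459 with an estimated correlation), including the oxidase gene ERO1 (1.07 ± 0.08) and ULI1 (1.75 ± 0.14).

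In total 3443 of 6171 genes changed by edgeR's quasi-likelihood test, 1723 higher and 1720 lower, of which 242 and 59 changed at least 2-fold. WT and PSD1 overexpression differed in the galactose genes and in PSD1 at once, so the 2 differences were not separable in this comparison. URA3, a pyrimidine gene often used as a plasmid marker, took 1.65% and 1.72% of counts in WT and 1.21% and 1.28% in PSD1 overexpression.

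The second comparison asked which genes depend on PDR3 while PSD1 is overexpressed. PDR3 was 404-fold lower in pdr3Δ (-8.66 ± 0.16, edgeR adjusted p = 1.19e-09), and CIS1 and PDR5, which had risen with PSD1, were far lower. CIS1 was 58.1-fold lower (-5.86 ± 0.13, adjusted p = 3.54e-09) and PDR5 was 16.9-fold lower (-4.08 ± 0.09, adjusted p = 3.83e-09). Most other changes were small, and 36 of 37 respiratory and 99 of 137 ribosomal protein genes were higher in pdr3Δ than in PSD1 overexpression (adjusted p = 0.28 with an estimated correlation for both lists). PSD1 itself was 1.68-fold lower (-0.75 ± 0.09, adjusted p = 0.000668), so the PSD1 dose differed between the groups compared. PDR1 stood at -0.04 ± 0.05 (adjusted p = 0.616) and TOM70 at -0.04 ± 0.06 (adjusted p = 0.706), while MSP1 fell by 0.21 ± 0.05 (adjusted p = 0.0228). The MSP1 call was lost without PSD1 overexpression library 1 (adjusted p = 0.108) or 2 (0.138), without pdr3Δ library 2 (0.165), and with DESeq2 (0.0544) or FPKM (0.061).

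Among genes above the fixed level, the largest falls after those were YGR035C (-4.25 ± 0.20), PDR15/YDR406W-A (-3.11 ± 0.10), the aldehyde reductase gene ARI1 (-2.06 ± 0.10), YOL150C (-1.86 ± 0.10), LAF1 (-1.84 ± 0.07), GRE2 (-1.74 ± 0.07), ULI1 (-1.59 ± 0.14) and BDH2 (-1.58 ± 0.08). YOL150C overlaps GRE2 on the opposite strand over 250 of its 312 bp, and with the strand setting not given the share of its reads that came from GRE2 is not known. Above the same level, the largest rises were YML090W (0.93 ± 0.12), HO, the mating type endonuclease gene (0.80 ± 0.05), the B-type cyclin gene CLB6 (0.77 ± 0.12), JEN1 (0.76 ± 0.05), YIG1 (0.75 ± 0.10), SPS4 (0.75 ± 0.14), YGR067C (0.75 ± 0.09) and SPO16 (0.73 ± 0.15). Adjusted p lay between 6.51e-08 and 0.00917 for these 16 genes. SPS4 lost its call without PSD1 overexpression library 2 (adjusted p = 0.0767), and SPO16 without PSD1 overexpression library 1 (0.0722) or 2 (0.0589) or pdr3Δ library 2 (0.059).

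Of the 23 Pdr1 and Pdr3 targets, which include PDR3, 18 were lower and none higher, 18 adjusted over the list alone (camera adjusted p = 1.62e-135; adjusted p = 0.0506 with an estimated correlation). The efflux pump genes SNQ2 (-1.12) and YOR1 (-0.99) and the lipid transfer gene PDR16 (-0.91) were among them. Of 16 genes of the unfolded protein response 12 were lower and none higher, 12 adjusted over the list alone (camera adjusted p = 4.99e-09; adjusted p = 0.237 with an estimated correlation), with ERO1 at -0.57 ± 0.07 and the nucleotide exchange factor gene SIL1 at -0.54 ± 0.06. Of 22 cytosolic heat shock genes 14 were lower, 17 adjusted over the list alone, and none higher (camera adjusted p = 3.8e-07; adjusted p = 0.28 with an estimated correlation), with SSA1 at -0.45 ± 0.07. Of 30 general stress genes 12 were lower and 1 higher, 14 and 1 adjusted over the list alone (camera adjusted p = 6.86e-05; adjusted p = 0.28 with an estimated correlation). Of 18 glycolysis genes 14 were lower and 1 higher, 15 and 1 adjusted over the list alone (camera adjusted p = 2.05e-10; adjusted p = 0.28 with an estimated correlation), with PDC1, pyruvate decarboxylase, at -0.87 ± 0.09.

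Of 37 respiratory chain and ATP synthase genes 36 were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 3.14e-25; adjusted p = 0.28 with an estimated correlation), with SDH2 at 0.46 ± 0.05 and ATP20 at 0.46 ± 0.05. Of 20 tricarboxylic acid cycle genes 12 were higher and none lower, 12 adjusted over the list alone (camera adjusted p = 6.1e-07; adjusted p = 0.28 with an estimated correlation). Of 137 ribosomal protein genes 99 were higher and 1 lower, 119 and 2 adjusted over the list alone (camera adjusted p = 5.7e-21; adjusted p = 0.28 with an estimated correlation). Of 62 ribosome biogenesis genes 46 were higher and none lower, 55 adjusted over the list alone (camera adjusted p = 9.48e-16; adjusted p = 0.332 with an estimated correlation). All 10 core histone genes were higher, 10 adjusted over the list alone (camera adjusted p = 1.41e-07; adjusted p = 0.28 with an estimated correlation), with HTB2 at 0.46 ± 0.06. Of 20 G1/S genes 14 were higher and none lower, 18 adjusted over the list alone (camera adjusted p = 1.12e-10; adjusted p = 0.0906 with an estimated correlation), with RNR1 at 0.64 ± 0.05. Of 38 import genes 2 were higher and 3 lower, 1 and 0 adjusted over the list alone (camera adjusted p = 0.587; adjusted p = 0.681 with an estimated correlation). Of 11 galactose genes 3 were higher and none lower, 3 adjusted over the list alone (camera adjusted p = 0.0199; adjusted p = 0.411 with an estimated correlation), GCY1 (0.35 ± 0.05), GAL3 (0.25 ± 0.04) and GAL80 (0.24 ± 0.05).

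**Figure D2:**
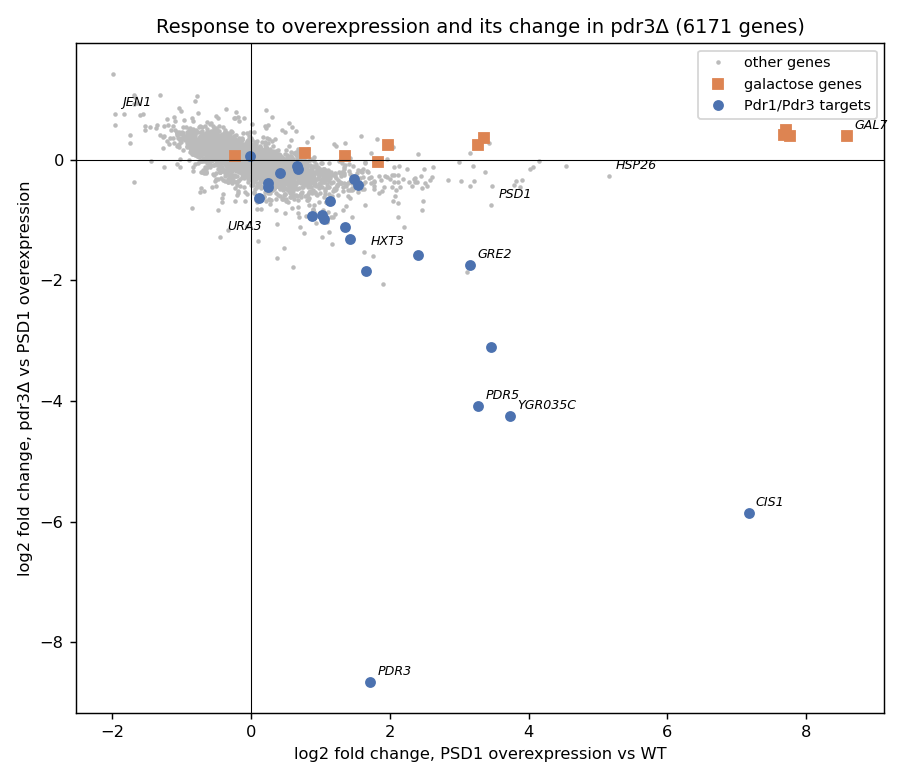
Log2 fold change of 6171 genes in PSD1 overexpression against WT (horizontal axis) and in pdr3Δ against PSD1 overexpression (vertical axis), with Pdr1 and Pdr3 targets as blue circles and galactose genes as orange squares. Among the targets CIS1, PDR5 and YGR035C lie at the lower right, galactose genes lie near 0 on the vertical axis, and both axes share the PSD1 overexpression libraries, which alone gives a downward slope.

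In total 1291 genes changed by edgeR's quasi-likelihood test, 728 higher and 563 lower, but only 1 rose and 25 fell at least 2-fold. The count fell by more than 1.5 times when any overexpressing library was left out, to 535 or 233 without PSD1 overexpression library 1 or 2 and to 796 or 615 without pdr3Δ library 1 or 2. It was 814 with DESeq2 and 825 with FPKM values, and those settings called 62.4% and 60.6% of the same genes.

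Of the 1723 genes higher in PSD1 overexpression than in WT, 482 were lower in pdr3Δ than in PSD1 overexpression, which is 85.6% of the genes that were lower. Of the 1720 lower genes, 670 were higher in pdr3Δ, 92% of those that were higher. Both comparisons used the same PSD1 overexpression libraries. Independent lists of the same sizes would share 157.2 and 202.9. Simulated libraries with no changed genes gave means of 0.1 and 0.15 over 20 draws, low because so few genes were called in them (1.25 and 1.7), so part of the excess could come from the shared libraries. With library 1 compared with WT and library 2 with pdr3Δ, a split chosen after the data were seen, 189 and 281 genes were shared where independent lists would share 48.4 and 69.8. With the libraries exchanged they were 125 and 112, against 31.4 and 27. The covariance of the fold changes was -0.089, against a simulated -0.00858 and against -0.0831 and -0.0798 in the 2 splits, and their correlation across genes, which are not independent replicates, was -0.553 against -0.512. The 482 fell to 204 or 122 without PSD1 overexpression library 1 or 2 and to 272 or 241 without pdr3Δ library 1 or 2. The 670 fell to 291, 95, 435 and 328 in the same order.

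The third comparison asked what remained of the response in cells without PDR3. In pdr3Δ with PSD1 overexpression 22 of 22 heat shock and 26 of 30 general stress genes were above WT, and 136 of 137 ribosomal protein and 36 of 37 respiratory genes were below it. With an estimated correlation none of these lists passed (adjusted p = 0.0693 to 0.366). Of 23 Pdr1 and Pdr3 targets 10 were above WT and 5 below. PDR3 was 123-fold lower than in WT (-6.94 ± 0.19, edgeR adjusted p = 4.99e-09) and PSD1 was 6.55-fold higher (2.71 ± 0.09, adjusted p = 2.17e-08). PDR5 was below WT (-0.81 ± 0.09, adjusted p = 5.45e-05). CIS1 was 2.48-fold above WT (1.31 ± 0.34, adjusted p = 0.0113), at 24 and 33 counts against 12 and 11, and lost its call without WT library 2 (adjusted p = 0.0607) or pdr3Δ library 2 (0.0724). MSP1 stood at -0.01 ± 0.05 (adjusted p = 0.93), PDR1 at 0.22 ± 0.05 (adjusted p = 0.00422) and TOM70 at -0.27 ± 0.06 (adjusted p = 0.00651), and the TOM70 call was lost without pdr3Δ library 2 (0.0533).

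Among genes above the fixed level, the largest rises were again GAL7 (8.99 ± 0.31), GAL2 (8.20 ± 0.26), GAL10 (8.15 ± 0.24), GAL1 (8.09 ± 0.27), HSP26 (4.88 ± 0.16), SIP18 (4.44 ± 0.22), GRE1 (4.14 ± 0.30) and YMR175W-A (3.94 ± 0.34). Above the same level, the largest falls after PDR3 were URA3 (-1.73 ± 0.12), CWP1 (-1.47 ± 0.11), YNR066C (-1.46 ± 0.14), ADH2 (-1.34 ± 0.14), the mannosyltransferase gene KTR2 (-1.26 ± 0.06), the hexose transporter gene HXT2 (-1.21 ± 0.13), JEN1 (-1.20 ± 0.05) and YNR065C (-1.15 ± 0.10). Adjusted p lay between 7.32e-09 and 4.2e-05 for these 16 genes. URA3 (YEL021W, chromosome V, 116167 to 116970) took 0.44% and 0.59% of counts in the pdr3Δ libraries, against 1.65% and 1.72% in WT. GAL1 had 101214 and 92225 counts in the pdr3Δ libraries.

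All 22 cytosolic heat shock genes were higher than in WT, 22 adjusted over the list alone (camera adjusted p = 2.51e-70; adjusted p = 0.0718 with an estimated correlation), with SSA3 at 3.86 ± 0.05. Of 30 general stress genes 26 were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 1.47e-51; adjusted p = 0.0693 with an estimated correlation), and of 32 proteasome genes 29 were higher and none lower, 30 adjusted over the list alone (camera adjusted p = 2.77e-05; adjusted p = 0.378 with an estimated correlation). Of 37 respiratory genes 36 were lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 1.32e-14; adjusted p = 0.366 with an estimated correlation). Of 20 tricarboxylic acid cycle genes 18 were lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 6.11e-09; adjusted p = 0.282 with an estimated correlation). Of 137 ribosomal protein genes 136 were lower and none higher, 136 adjusted over the list alone (camera adjusted p = 8.82e-50; adjusted p = 0.282 with an estimated correlation). Of 20 mitochondrial chaperones and proteases 7 were higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.00646; adjusted p = 0.366 with an estimated correlation), with HSP78 at 1.53 ± 0.07. Of 11 galactose genes 10 were higher and none lower, 10 and 1 adjusted over the list alone (camera adjusted p = 3.57e-59; adjusted p = 0.0693 with an estimated correlation). Glucose-repressed and Snf1-dependent genes were lower for 8 of 18 and higher for 1, the same adjusted over the list alone (camera adjusted p = 0.0036, or 0.475 with an estimated correlation).

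Of the 23 Pdr1 and Pdr3 targets 10 were higher and 5 lower than in WT, the same adjusted over the list alone (camera adjusted p = 0.966; adjusted p = 0.985 with an estimated correlation). Their median log2 fold change was 0.12 and their mean -0.04, which includes the deleted PDR3, and the camera test pointed up. GRE2 stayed above WT (1.41 ± 0.09), as did RPN4, the proteasome gene activator (0.51 ± 0.05). Of 16 unfolded protein response genes 2 were higher and 5 lower, the same adjusted over the list alone (camera adjusted p = 0.397; adjusted p = 0.78 with an estimated correlation). ERO1 stayed above WT (0.50 ± 0.08) and SIL1 lay below it (-0.34 ± 0.06).

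**Figure D3:**
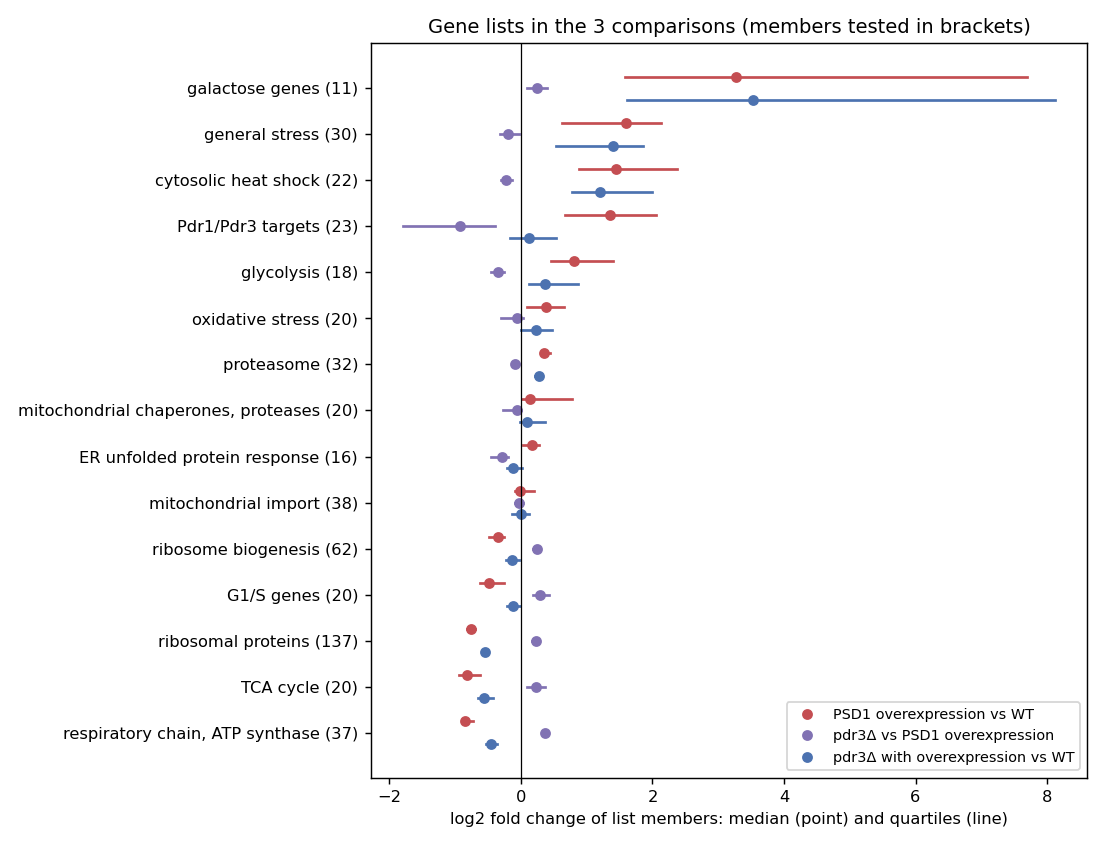
Median log2 fold change (points) and quartiles (lines) of the members of 15 gene lists in the 3 comparisons, with the number of members tested in brackets. Pdr1 and Pdr3 targets had a median of 1.35 in PSD1 overexpression against WT and 0.12 in pdr3Δ with PSD1 overexpression against WT, whereas cytosolic heat shock genes had medians of 1.45 and 1.20.

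Expressed as a share of the log2 rise in PSD1 overexpression against WT, the 14 Pdr1 and Pdr3 targets induced at least 2-fold kept a median of 14.2% in pdr3Δ (quartiles 6.8% to 38.8%). Of these targets 3 lay below WT. A pdr3Δ sample without PSD1 overexpression was not measured. Lost induction therefore cannot be told apart from an effect of the deletion that needs no overexpression. WT also differed in the galactose genes, and a rise that came from the sugar could be kept whatever the PDR3 or PSD1 level. The 219 other genes induced at least 2-fold kept 80.2% (quartiles 67.2% to 88%), a difference with a two-sided permutation p of 1e-05 across genes, the smallest that 100000 permutations can give. Of the 219, 23 kept under 50%, among them the unfolded protein response genes ULI1 (9.4%) and ERO1 (46.4%), while YET2 kept 56.1%. Over list members called at any size, where small changes make the share unstable, 9 unfolded protein response genes kept a median of 8.2% (quartiles -48.9% to 46.4%), 16 G1/S genes 34.1%, 37 respiratory genes 54.9%, 18 glycolysis genes 55.6% and 22 heat shock genes 84.4%. Genes are not independent replicates, and PDR3, PSD1, URA3 and 7 galactose genes were left out. The 59 genes repressed at least 2-fold kept 62.8%. In total 2415 genes differed between pdr3Δ with PSD1 overexpression and WT by edgeR's quasi-likelihood test, 1210 higher and 1205 lower, of which 138 and 25 differed at least 2-fold. Of these, 1111 were higher and 1058 lower in both overexpressing groups, where independent lists would share 337.8 and 335.9 and simulated libraries with no changed genes, with few calls, gave 0.25 each. Both used the same WT libraries, so part of this excess could come from them.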

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

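The tests of plasmid copies, the pyrimidine pathway, galactose status and PSD1 dose were chosen after the results were seen, as was the split of the shared libraries, and only the covariance against simulated libraries was set before. PDR3, PDR5 and SIL1 drew attention because each was called in opposite directions against WT in the 2 overexpressing groups, higher with PDR3 present and lower without it. The difference between those groups, tested with edgeR, was -8.66 for PDR3, the deleted gene, -4.08 for PDR5 and -0.54 for SIL1, which encodes a nucleotide exchange factor of the endoplasmic reticulum. Over all tested genes 11 were higher than WT in PSD1 overexpression and lower in pdr3Δ, and 1, SUR7, was the reverse. The 11, named after their values were seen, also held the drug and polyamine exporter gene TPO1 and the sphingolipid gene IPT1.

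GAL1, GAL2, GAL7 and GAL10 were nearly silent in WT, where they stood at a median of 0.471% of their level in PSD1 overexpression (0.262% to 0.49% across the 4 genes). The 2 WT libraries differed, as in GAL1 (484 and 230 counts) and GAL7 (182 and 51). Other galactose genes were lower in WT but not silent. These were GAL80 (95.92 against 374.9 CPM), GCY1 (99.86 against 1025) and GAL3 (31.02 against 300.4). The labels give 2% galactose for 4 h for every sample, WT included, but mark the induction plus or minus, so the low level could mean that WT cells received none, and without an induced sample lacking PSD1 overexpression this cannot be told. Reads from a plasmid GAL promoter would not raise genes elsewhere, yet GAL2, GAL3, GAL7, GAL80 and GCY1 rose by a median of 3.36, which excludes them as the whole cause. If PSD1 itself raised the galactose genes they could be lower where PSD1 was lower, but their median in pdr3Δ against PSD1 overexpression was 0.40, and the deletion differed in the same libraries, so this cannot be told. Some of the changes against WT may therefore come from the sugar rather than from PSD1.

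The response was smaller in pdr3Δ, where PSD1 was also 1.68-fold lower. A lower PSD1 dose alone could be expected to shrink all genes that PSD1 induced alike. Pdr1 and Pdr3 targets kept 14.2% of their log2 induction and other induced genes 80.2%. This argues against an equal dose effect only if PSD1 induced both sets. Genes induced by the sugar could keep their change at any PSD1 dose, so an equal effect on the genes that PSD1 induced is not excluded. A dose effect that is stronger for some genes also stays open, since 23 of the 219 other induced genes kept under 50%, ULI1 only 9.4%. Some of the 23 have a response element for Pdr1 and Pdr3 upstream and could be unlisted targets. These are HXT3, RTS3, ICY1, LAC1, ARE2, MIG2 and TVS1, whereas ULI1, ARI1 and HXT4 have none. For induced genes outside the target list dose and deletion cannot be told apart because they differ in the same libraries. Chance values of the shared PSD1 overexpression libraries, at the spread between samples of a group, were excluded as the whole cause. The covariance of the fold changes was 10.4 times the simulated value. It was 8.53 times without Pdr1 and Pdr3 targets, PSD1, URA3 and galactose genes, a restriction chosen after the result. It stayed at -0.0831 and -0.0798 when each comparison took its own PSD1 overexpression library. A deviation common to both PSD1 overexpression libraries, as from a single culture, is in neither check and is not excluded.

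URA3 fell by 1.28 ± 0.12 in pdr3Δ against PSD1 overexpression (edgeR adjusted p = 0.000167). Fewer copies of a URA3 plasmid carrying PSD1 could lower both, and PSD1 above its WT level was lower by a log2 ratio of -0.85, which fits, although no read was assigned to a plasmid and URA3 was most abundant in WT. For lower activity of Ppr1, the activator of pyrimidine genes, URA1, URA4 and URA10 were read, with a median of 0.15 (SD 0.44). URA1 rose (0.58 ± 0.06, edgeR adjusted p = 0.000215) and URA4 was not called (0.15 ± 0.05, adjusted p = 0.078). URA10 fell (-0.31 ± 0.09, adjusted p = 0.0349). The rise of URA1 argues against a fall common to these genes, but with mixed directions lower Ppr1 activity was not excluded. Weaker galactose induction was excluded because the smallest change among GAL1, GAL2, GAL7 and GAL10 was 0.39. The biological alternative, an effect of the PDR3 deletion on URA3, was not tested apart from these.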

How the results depend on the processing

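Library sizes without PSD1, URA3 and the galactose genes and a split of the PSD1 overexpression libraries were the alternatives chosen after the data were seen. The first gave 3441, 1289 and 2414 changed genes, within 1.5 times of the values reported. Library sizes without PSD1, ribosomal RNA and mitochondrial genome genes gave the same counts. TMM scaling was applied after the sizes were changed and largely cancels such a change. These 2 settings therefore could not show whether the genes left out matter. No result reversed. Genes changed in pdr3Δ against PSD1 overexpression numbered 814 with DESeq2 and 825 or 829 with FPKM + 1 or + 0.1, induced genes lower in pdr3Δ 290 with DESeq2, and repressed genes higher in pdr3Δ 416 or 417 with FPKM. The cause was not tested. With a 2-fold minimum, fewer by construction, the changed genes were 301, 26 and 163 and the shared genes 18 and 1. Camera with an estimated correlation called 0, 0 and 0 gene lists against 19, 20 and 15, and fry, which tests a different null hypothesis, called 29 in PSD1 overexpression against WT. Leaving out 1 library gave 2732 to 3388, 233 to 1533 and 1801 to 2226 changed genes, 122 to 570 induced genes lower in pdr3Δ and 95 to 753 repressed genes higher. It left 19 to 20, 18 to 20 and 14 to 18 lists. With 1 PSD1 overexpression library for each comparison, 189 or 125 induced genes were lower in pdr3Δ and 281 or 112 repressed genes higher. The lone sample left was assumed to vary like the other groups. The cause of these shifts beyond fewer samples was not tested. A replicate block gave 3491, 1393 and 2483 changed genes, 524 and 708 shared genes and 20, 19 and 15 lists, and it moved no count by more than 1.5 times. Deviations of same-numbered libraries correlated at 0.041, 0.194 and -0.02, and although the titles number the replicates in every group, they do not say what a number stands for, so pairing was not established. In simulated data small changes were the least often found, and changes of log2 0.25 were recovered for 32%, 36% and 44% of genes. Far fewer genes were changed there than were called in the measured data, so these shares may be too low for the latter.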

Other observations

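The gene families below and the genes named with them were chosen after their values were seen, from 18 families tested, whereas the tests of response elements were set before. Of 11 ADE genes, which act in purine synthesis, 10 were higher in PSD1 overexpression than in WT (camera adjusted p = 6e-04; adjusted p = 0.207 with an estimated correlation) and 9 were lower in pdr3Δ than in PSD1 overexpression (camera adjusted p = 3.6e-09; adjusted p = 0.0959 with an estimated correlation). ADE17, which acts late in the pathway, changed most (2.21 ± 0.10 and -1.12 ± 0.09). Of 36 autophagy genes, 28 were higher than WT (camera adjusted p = 0.00024; adjusted p = 0.393 with an estimated correlation), including the reticulophagy receptor gene ATG40 (1.33 ± 0.09), and 10 were lower in pdr3Δ than in PSD1 overexpression (camera adjusted p = 6.89e-05; adjusted p = 0.272 with an estimated correlation). Of 15 hexose transporter genes 4 were lower in pdr3Δ (camera adjusted p = 6.89e-05; adjusted p = 0.148 with an estimated correlation), among them HXT3 (-1.54 ± 0.09) and HXT4 (-1.28). Of 11 cell wall genes grouped by name (CWP, KTR, UTR2 and CRH1) 9 were lower and 1 higher in PSD1 overexpression (camera adjusted p = 0.000407; adjusted p = 0.207 with an estimated correlation). In pdr3Δ with PSD1 overexpression 7 were lower than in WT (camera adjusted p = 2.8e-05; adjusted p = 0.271 with an estimated correlation). The group includes CWP1 and KTR2, already named among the largest falls, so these p-values are no independent support. The 11 genes do not stand for cell wall genes as a class. GAL1 and URA3 also differed between WT and the other groups.

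The hypothesis tested was that genes which were lower in pdr3Δ, outside the fixed list of targets, carry a response element for Pdr1 and Pdr3 upstream. Of 15 such genes that fell at least 2-fold 2 (13.3%) had an element, against 92 of 5519 background genes (1.7%, Fisher exact p = 0.026, adjusted 0.0433 over the 5 sets). Of 520 genes that fell less, 28 (5.4%) had an element (Fisher exact p = 6.89e-07, adjusted 1.72e-06). Of 721 genes that rose 13 (1.8%) did, against 109 of 5333 (2%) in the background for that set (Fisher exact p = 0.778). In the fixed list 17 of 22 genes (77.3%) did. The enrichment fits direct binding for some of these genes, which could include HXT3, RTS3 (-1.40 ± 0.08) and the ceramide synthase gene LAC1 (-0.91), but most of the 520 genes had no element, and binding was not measured.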
